A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

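Total RNA of 4 Halobacterium salinarum NRC-1 samples (0, 0.5, 0.75 and 1.5 mM NiSO4 for 5 h) was compared with a standard mid-log reference RNA on 8 two-colour spotted arrays, per the labels, each sample once in Alexa 532 and once in Alexa 647. The values used are the authors' processed table, which holds 1 signed log ratio per spot for 10752 spots. Per the labels, the sample is in channel 1 and is described as set against the reference, so the direction sample over reference is likely and was not stated. The dye partners of the 3 nickel RNAs correlated positively, as they would after all ratios had been turned the same way. A bias of spots or dyes shared by all arrays would also make unturned partners correlate, so this does not settle the turning. The higher ratios at the last spot numbers had the same sign in both orientations. Were ratios unturned, averaging dye partners would keep such bias and lose the sample's difference from the reference, which was not tested. The base of the deposited log ratios is not stated: log10 was inferred from their spread, since in log2 the repeat spots would differ implausibly little. The design written beforehand assumed log2, and the deposited log10 units were kept; adjusted p-values do not depend on the base, folds do. Scanner, background correction, normalization and spot filters are not given in the sources used here. Without intensities in the table used here, signal over background was not analysed here, and the number of arrays limits the precision.

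Spots missing numbered 992 on each Alexa 532 array and 831 on each Alexa 647 array. Exact zeros stood at 2126 spots of the no-nickel Alexa 532 array, 1348 spots of the 0.5 mM Alexa 532 array and 1 spot of the no-nickel Alexa 647 array, and at 0 spots elsewhere. Of the zeros on the first array 46% lay in the last 2 of 12 runs of spot numbers, and at those spots the 0.75 and 1.5 mM arrays had a mean ratio of 0.239, against 0.0668 at other spots. They were therefore taken as spots without an estimate. Deposited medians ran from 0.0148 to 0.137. Each feature was printed as 4 spots, an adjacent pair and the same pair 5376 spot numbers later, a layout that held for all 133 named genes. Spots of a feature were averaged, features with a value on all 8 arrays were kept (2368 of 2688), and each array was centred on its median over these. Without centring, the median of all features at 1.5 mM minus no nickel was 0.0391 (0.13 on the log2 scale), so changes are relative to that median.

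Gene names are those of the platform annotation, which can be old: 532 spots have 1 gene symbol, 0 have several and 10220 are unnamed here. Of the 133 symbols 133, and of their Entrez identifiers 0, were found in a gene table of another strain (assembly of strain 91-R6), which was used for nothing else. Genome coordinates were not used here. The 22 gene lists were fixed before the data were examined and matched by symbol, since product descriptions were not used here.

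The 2 arrays of an RNA were averaged to 1 value. The dose trend was a linear term in mM, and any nickel against none a 2-level term, both fitted over the 4 RNA samples with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, robust off, Benjamini-Hochberg adjusted p under 0.05). The trend fit has 2 residual degrees of freedom per feature, and eBayes gave every feature the same spread, with 4736 degrees of freedom in total; the any-nickel fit had a median of 24.35. Both fits assume that the lone no-nickel RNA varies like the others, which its dye partners (r = -0.135) speak against. The any-nickel p-values are therefore too small. The trend p-values are likely too small as well, since that RNA stands at an end of the dose axis. Nothing in the labels says that doses came from several cultures, so p-values measure only the spread between these 4 samples around a line or a mean. Each dose was set against no nickel within each dye orientation by a size rule of 2-fold (0.301 log10 units) in both, with no p. Gene lists with at least 3 members were tested with camera (preset correlation 0.01, also estimated) and fry, and their medians were placed among 10000 random lists of the same size. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

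The rule for named genes, fixed beforehand, took the 10 largest rises and 10 largest falls meeting the size rule at 1.5 mM, 5 each way at 0.5 and 0.75 mM, the 5 largest effects each way among calls of the trend and of any nickel, and the 2 largest each way per list at 1.5 mM. Since only 1 feature met the size rule, and it was unnamed, the genes taken by this rule come from the trend and any-nickel calls and from the lists. Mobile elements were left out of these picks. The text names further genes, called and not called, which were chosen after their values were seen.

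The fits were tested on 20 simulated data sets of 2368 features with 200 changed. A slope of 0.15 log10 units per mM was recovered in 83.55% and one of 0.3 in 100% of changed features by the trend fit, with a false share of 4.06%. A step of 0.15 was recovered in 57.95% and one of 0.3 in 100% by the any-nickel fit, with a false share of 3.72%. The camera step called 20 of 20 changed lists and 1 of 20 unchanged lists. These simulations give every RNA the same independent noise.

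Alternatives fixed beforehand were values as deposited, arrays scaled to a common spread, the median of spots, features with every spot measured, robust eBayes, other dose scales, other size rules, 8 arrays with the dye orientation as a term, each orientation alone and each RNA left out. Added after seeing the data were the centring of each of 12 runs of spots, exact zeros kept as values, and fits without the no-nickel Alexa 647 array.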

Results

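Gene expression was measured in the halophilic archaeon Halobacterium salinarum NRC-1 after exposure to nickel sulfate (NiSO4), a metal salt that stresses the cells. Mid-log cultures in complex medium were kept for 5 h without nickel or with 0.5, 0.75 or 1.5 mM NiSO4, which gave 4 RNA samples, 1 per dose. Each RNA was hybridised on 2 arrays against a standard mid-log reference RNA, with the sample labelled by the dye Alexa 532 on the first array and by Alexa 647 on the second, so that 8 arrays were obtained. The 2 arrays of a dose are a technical dye swap and count as 1 replicate. Values are log10 ratios of sample over reference, with each array centred on its median. The base and the direction of the ratios are inferred and not stated, and every fold and fold rule given here rests on base 10. Whether the ratios of dye-swapped arrays were turned the same way is not stated either, and every result here assumes it. Of 2688 features with 4 spots each, 2368 had a value on all 8 arrays, and 129 of these carried a gene symbol. For arrays, their number limits the precision: a dose has no replicate RNA, so no dose was tested against the no-nickel RNA by itself.

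The 2 arrays of an RNA correlated across features at r = 0.624 for 0.5 mM, 0.689 for 0.75 mM and 0.79 for 1.5 mM, but at -0.135 for the no-nickel RNA. The no-nickel array with the sample in Alexa 532 correlated with the 6 nickel arrays at 0.556 to 0.751, whereas its Alexa 647 partner did so at -0.0611 to 0.188. Features are not independent replicates, so these correlations carry no p. Repeat spots of a feature had a median SD of 0.109 on that Alexa 647 array and of 0.0493 to 0.0892 on the other 7. Ratios were higher at the first and last spot numbers, and differences between 12 runs of consecutive spot numbers made up 15.8% to 33.2% of the variance of the spots.

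**Figure D1:**
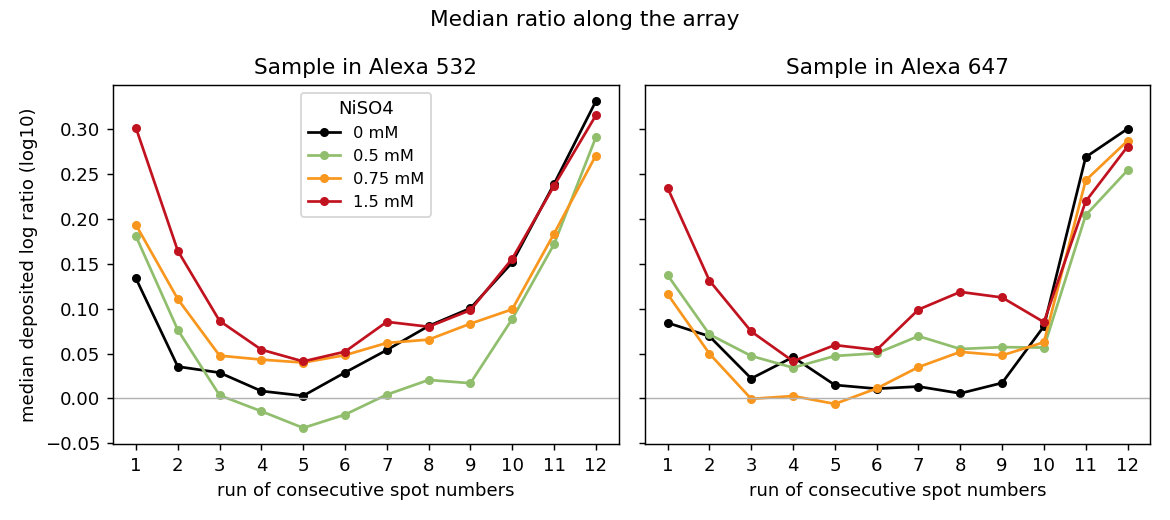
Median deposited log ratio (y axis, log10) in each of 12 consecutive runs of 896 spot numbers (x axis), by NiSO4 dose (coloured lines), with the sample in Alexa 532 on the left and in Alexa 647 on the right. On the no-nickel Alexa 532 array the run medians ran from 0.00284 in run 5 to 0.331 in run 12, and run 1 of the 1.5 mM arrays stood at 0.302 and 0.235.

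The first question was which genes followed the nickel dose. The truA gene, which encodes a tRNA pseudouridine synthase, rose with dose by 0.183 ± 0.0389 log10 units per mM (SE, 4 RNA samples; limma adjusted p = 0.00035), and its level at 1.5 mM was 1.89-fold that without nickel. This SE is shared by all features, and the trend p-values are likely too small, because the no-nickel RNA is assumed to vary like the others. The first spots of truA lie in run 1, whose median rose from 0.134 and 0.0842 without nickel to 0.302 and 0.235 at 1.5 mM. With runs of spots centred its slope was 0.127 and still passed. Further genes of metabolism passed with a positive slope, namely mch, which encodes methenyltetrahydromethanopterin cyclohydrolase, at 0.159 per mM (adjusted p = 0.00248), the histidine degradation gene hutI at 0.122 (adjusted p = 0.0223) and nadA, which encodes quinolinate synthase of NAD synthesis, at 0.114 (adjusted p = 0.0341). Most of the difference of mch was there at the lowest dose (0.201, 0.169 and 0.263 at 0.5, 0.75 and 1.5 mM), as was that of hutI (0.129, 0.0877 and 0.199) and of nadA (0.109, 0.126 and 0.18). The glutamate dehydrogenase gene gdhB fell by 0.169 per mM (adjusted p = 0.00114) and reached 0.537 of its no-nickel level at 1.5 mM. The gene of the ferritin-like DNA-protecting protein, dpsA, fell by 0.157 per mM (adjusted p = 0.00299), the transducer gene htr18 by 0.138 (adjusted p = 0.0099), and the thiamine synthesis gene thiD by 0.137 (adjusted p = 0.0104). The proteasome alpha subunit gene psmA passed the trend test too (slope -0.127, adjusted p = 0.017), but as a step rather than with dose, at -0.22, -0.223 and -0.216 from the lowest to the highest dose; gdhB stood at -0.175, -0.181 and -0.27 and htr18 at -0.123, -0.107 and -0.22.

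Another 12 named genes fell with dose, with adjusted p from 0.0221 for glyA to 0.0455 for psmB. They comprised psmB of the proteasome beta subunit, glyA (serine hydroxymethyltransferase), glnA (glutamine synthetase), the amino-acid synthesis genes asd and pheA, and the tRNA synthetase genes ileS and proS. They further comprised sdhC of succinate dehydrogenase, the sensory rhodopsin gene sop1, the cofactor genes moaA and thiC, and the protein export gene secF. The level of these 12 at 1.5 mM ranged from 0.639 for glyA to 0.702 for secF of the no-nickel level. All 21 lay on the called side of the no-nickel RNA in 3 of 3 nickel RNAs, which a trend call already favours, so that it adds little support. Of the 4 rising genes and the 5 with the steepest falls, truA, mch, gdhB, dpsA, htr18, thiD and psmA lay on the same side of the no-nickel RNA at every dose in both dye orientations. The genes hutI and nadA did not in single arrays, and at 0.5 mM in Alexa 532 they differed from the no-nickel RNA by -0.0811 and -0.042. Over all 21 genes, 12 lay on the called side at every dose in both orientations. Of the 12 further falling genes these were psmB, glnA, pheA, proS and thiC only. At 0.5 mM in Alexa 532, glyA stood at 0.114 and sdhC at 0.00944.

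Over all 2368 features, 319 passed limma's adjusted p of 0.05, 184 upward (57.7%) and 135 downward, and 709 had an unadjusted p under 0.05. With values as deposited, not centred, 230 of 234 calls were upward (98.3%), and 5 of the 21 named genes were still called. Since the direction of the ratios is not stated, with every ratio turned these upward shares would be 42.3% and 1.71%. In limma fits with the Alexa 532 arrays alone, the Alexa 647 arrays alone, the no-nickel Alexa 647 array left out or 8 arrays as the unit, 0 features passed, with 260, 608, 407 and 533 at an unadjusted p under 0.05, and 1 passed with the arrays scaled to a common spread. Without that no-nickel array the slope was 0.00862 for hutI, 0.0362 for nadA, 0.083 for mch, -0.06 for dpsA, -0.0595 for thiD and 0.0461 for glyA, beside 0.173 for truA and -0.139 for gdhB. The count was 11 without the no-nickel RNA, where 0 of the 21 named genes were called and the slope was 0.00489 for psmA, 0.0767 for mch, 0.071 for nadA, -0.1 for gdhB, -0.103 for dpsA and -0.0827 for thiD. It was 512 without the 0.5 mM RNA, 102 without the 0.75 mM RNA and 137 without the 1.5 mM RNA, where the slope was -0.318 for psmA, 0.25 for mch, 0.175 for nadA, -0.257 for gdhB, -0.276 for dpsA and -0.231 for thiD.

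**Figure D2:**
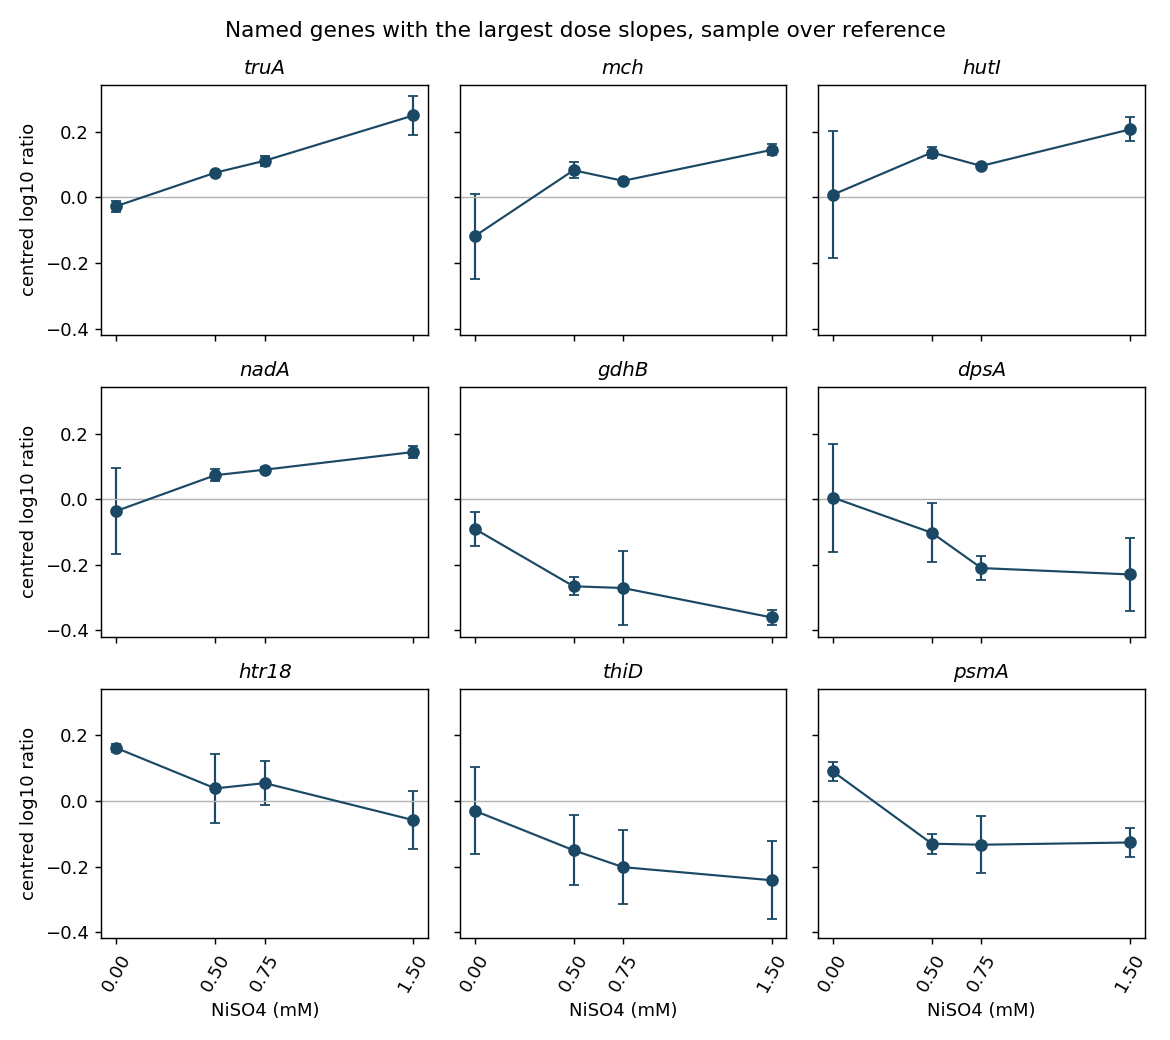
Centred log10 ratio of sample over reference (y axis) against NiSO4 dose in mM (x axis) for the 4 named genes that rose and the 5 that fell most steeply with dose. Points are the mean of the 2 arrays of an RNA and bars end at the values of the 2 arrays; truA went from -0.0271 to 0.249, gdhB from -0.0901 to -0.36, and the widest bar is that of hutI without nickel.

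The second question was which genes differed between the 3 nickel RNAs together and the no-nickel RNA. The proteasome gene psmA was lower with nickel by a difference of -0.22 ± 0.043 log10 units (SE; limma adjusted p = 0.00318), with nearly the same value at each dose (-0.22, -0.223 and -0.216). The difference was -0.209 for gdhB (adjusted p = 0.00749), -0.186 for dpsA (adjusted p = 0.0188), -0.172 for glyA (adjusted p = 0.017) and -0.168 for thiD (adjusted p = 0.0217). It was 0.211 for mch (adjusted p = 0.00654), 0.172 for truA (adjusted p = 0.0382), 0.161 for the bacterio-opsin activator gene bat (adjusted p = 0.0212) and 0.138 for nadA (adjusted p = 0.0466). Another 7 named genes were lower, namely psmB, sdhC, glnA, proS, htr18, the chemotaxis regulator gene cheY and the protein export gene secY, from -0.139 for secY (adjusted p = 0.0428) to -0.153 for cheY (adjusted p = 0.0259). All 16 genes lay on the same side in 3 of 3 nickel RNAs, which such a call nearly requires, so that it adds no support. The fit takes its spread from the 3 nickel RNAs and assumes that the lone no-nickel RNA varies like them, yet the arrays of the no-nickel RNA differed with an SD of 0.182 across features, against 0.0959 to 0.102 for the nickel RNAs. The p-values are therefore too small, and these differences are given as values and not as calls against that RNA.

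The differences of bat, nadA, glyA and cheY rested on the Alexa 647 arrays. At 1.5 mM the difference of bat was 0.0191 in Alexa 532 and 0.327 in Alexa 647, that of nadA 0.0649 and 0.295, that of glyA 0.0261 and -0.415, and that of cheY 0.0558 and -0.359. With the Alexa 532 arrays alone bat stood at -0.00833, nadA at 0.00782, glyA at 0.0408 and cheY at 0.0299, while mch was at 0.0789, gdhB at -0.103, dpsA at -0.1 and psmA at -0.137, against 0.343, -0.315, -0.271 and -0.303 with the Alexa 647 arrays alone. The psmA difference at 1.5 mM was -0.143 in Alexa 532 and -0.29 in Alexa 647. That of sdhC was -0.0708 and -0.28, and that of psmB -0.0896 and -0.245, so these too were larger in Alexa 647. At 0.5 mM in Alexa 532 they stood at 0.00944 and -0.00491. The 2 orientations lay closer for proS (-0.158 and -0.191 at 1.5 mM), and truA was larger in Alexa 532 (0.318 and 0.235). Across features, 267 passed limma's adjusted p of 0.05, 142 upward (53.2%) and 125 downward, and 715 had an unadjusted p under 0.05. The upward share was 41.9% when each run of spots was centred, a setting chosen after seeing the data, in which truA no longer passed (0.104). With every ratio turned these shares would be 46.8% and 58.1%. Of the 16 named genes 0 passed with 8 arrays as the unit and the orientation as a term, 0 with values as deposited, 0 with the Alexa 532 arrays alone, 9 without the 0.75 mM RNA and 11 without the 1.5 mM RNA, where truA (0.12) and nadA (0.117) did not. The count was 28 with the Alexa 532 arrays alone, 1065 with the Alexa 647 arrays alone, 1 with values as deposited and 15 with 8 arrays as the unit. Without the no-nickel Alexa 647 array 392 features passed, of which 100 were among the 267, and 4 of the 16 named genes still passed; the difference was then 0.0811 for mch, 0.00571 for nadA, -0.0208 for dpsA, -0.0363 for thiD, -0.0134 for bat, 0.115 for glyA and 0.0146 for cheY.

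Each dose was also set against the no-nickel RNA by size, with a change of 2-fold in the same direction in both orientations as the rule. At 0.5 mM 0 features met it, and psmA had the lowest named value, -0.16 in Alexa 532 and -0.28 in Alexa 647, a mean of 0.603 of the no-nickel level. The highest named value was that of mch, at 0.047 and 0.355. At 0.75 mM again 0 features met the rule, with psmA at -0.107 and -0.34 and dpsA at -0.0863 and -0.344. At 1.5 mM 1 feature met it, an unnamed one at spot number 1985 that was 2.375-fold higher (0.375 and 0.376). No named gene did: truA came nearest upward at 0.318 and 0.235, and thiD downward at -0.198 and -0.226, with gdhB at -0.195 and -0.346. With 1.5-fold as the rule, truA was up and gdhB, dpsA and thiD were down at 1.5 mM, among 61 features. The differences in the 2 orientations correlated across features at -0.174 for 0.5 mM, -0.0102 for 0.75 mM and 0.177 for 1.5 mM. The median absolute difference of a feature was 0.0586, 0.057 and 0.0812 at the 3 doses, beside a median of 0.0648, 0.0595 and 0.0626 by which each orientation departed from that mean.

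**Figure D3:**
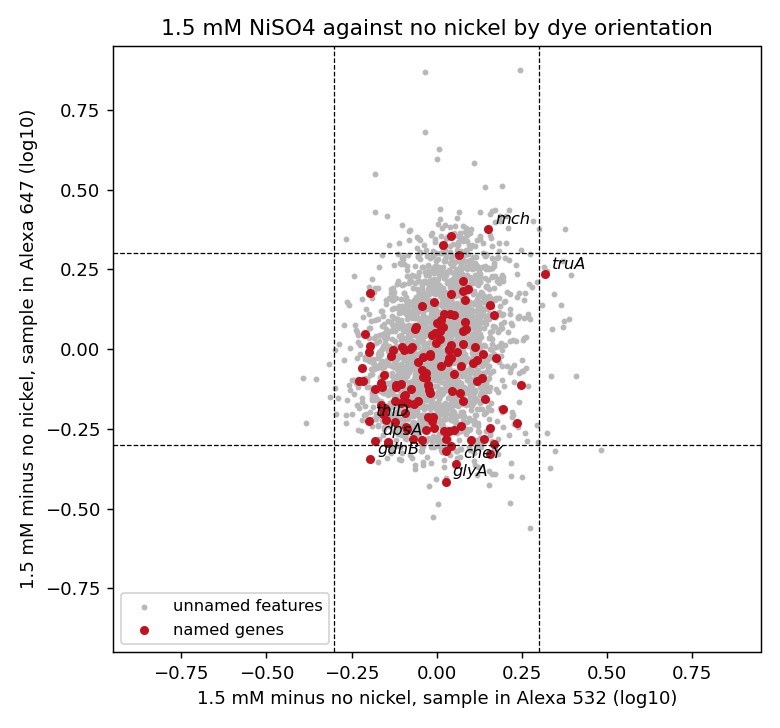
Difference between 1.5 mM NiSO4 and no nickel (log10) with the sample in Alexa 532 (x axis) and in Alexa 647 (y axis) for 2239 unnamed features (grey) and 129 named genes (red); dashed lines mark 2-fold. Values correlated at 0.177, and truA, at 0.318 and 0.235, lies beyond the dashed line on the x axis only.

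Gene lists fixed beforehand were compared with all other features along the dose by limma's camera test. Of 22 lists, 9 had at least 3 named genes. The proteasome subunit genes psmA and psmB were the 2 of 6 genes called in the list of chaperones, proteasome and proteolysis; the chaperone genes dnaK and dnaJ had slopes of -0.0189 and -0.0808 and pan1, a proteasome-activating ATPase gene, of 0.0465. The sixth member, panB, carries a name used for an enzyme of pantothenate synthesis. The list had an adjusted p of 0.15 by camera. In motility and taxis 1 of 11 genes fell, htr18, and 0 rose; cheB had a slope of -0.105 and htr8 of 0.0456, and the list had a camera adjusted p of 0.121. In arginine fermentation and anaerobic respiration 1 of 4 genes fell, moaA, while arcA and arcC had slopes of -0.0739 and -0.0356 (camera adjusted p = 0.121).

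None of the other 6 lists was called by camera either. In aminoacyl-tRNA synthetases and translation factors 2 of 13 genes fell, ileS and proS, and the highest slope was 0.0448 for glyS (camera adjusted p = 0.197). In the citrate cycle 1 of 7 genes fell, sdhC, with citZ at 0.0123 and icd at -0.0754 (camera adjusted p = 0.193). The 6 genes of cobalamin and heme synthesis had slopes from -0.0856 for cobN to -0.011 for hemL, and 0 passed (camera adjusted p = 0.15). Of the 4 genes of bacteriorhodopsin and retinal proteins, sop1 fell, sop2 had a slope of -0.0916 and bat one of 0.105 (camera adjusted p = 0.555). In histidine metabolism hutI rose, and its neighbours in the degradation pathway hutU and hutG had slopes of 0.09 and 0.0779 without passing. The histidine synthesis gene hisI had one of -0.0864, and the median slope of that list was -0.00273 while its mean was 0.0195 (camera adjusted p = 0.555, upward). The 8 genes of DNA replication and repair ranged from -0.032 for gyrA to 0.0347 for radB, with a median of 0.00457 (camera adjusted p = 0.974, downward).

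Camera gave 0 of 9 lists under an adjusted p of 0.05 and 2 under an unadjusted p of 0.05, motility (0.0174) and arginine fermentation (0.0268); with an estimated correlation the lowest adjusted p was 0.654, and by fry it was 0.0892. Adjusted over the list alone, the genes called were 2 for chaperones, 2 for motility, 3 for retinal proteins, 1 for arginine fermentation, 4 for tRNA synthetases, 2 for the citrate cycle, 1 for histidine and 0 for cobalamin and DNA repair. As a description of each dose without a test, the median of motility and taxis lay at the 0.35 percentile of 10000 random lists at 1.5 mM (median -0.111), at 0.25 at 0.75 mM and at 21.8 at 0.5 mM. That of chaperones and proteasome lay at 0.47 at 0.5 mM and at 2.66 at 1.5 mM. The random lists and the camera background came from all 2368 features, whereas list members are named genes. Nickel arrays lay below no nickel in every dose and orientation for 24.8% of named genes and 12.6% of unnamed features. They lay above it for 6.98% and 13.2%. Low percentiles and camera p may therefore in part reflect being a named gene.

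Lists with fewer than 3 named genes were given as values. In metal transport the cobalt transport gene cbiQ was the only member and had a slope of -0.0764 ± 0.0389 (SE; limma adjusted p = 0.166). Of the redox genes dpsA fell and msrA had a slope of -0.0544. The ribosomal protein genes rpl12p and rpmC had slopes of -0.0378 and -0.0741, the phosphate uptake regulator phoU of -0.00618, the ferredoxin gene fer2 of -0.081, and in the respiratory chain nuoL had -0.0382 beside sdhC, which fell. Gas vesicle proteins, ATP synthase, RNA polymerase, peptide transport, mobile elements, cell division and potassium transport had 0 named genes and were not analysed here.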

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

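Centring of runs of spots, exact zeros kept and the fits without the no-nickel Alexa 647 array were chosen after the data were seen. No list was called by camera under any of the 9 alternatives tried. The number of arrays, with 1 RNA per dose, limits every count here, and for the changes listed the cause was not tested. Features meeting the size rule, 0 at 0.5 and 0.75 mM and 1 at 1.5 mM, numbered 24, 18 and 61 with 1.5-fold and 6, 7 and 16 with 2-fold in the mean only. With a single orientation they numbered 28 to 112 at 0.5 mM, 6 to 87 at 0.75 mM and 24 to 185 at 1.5 mM. At 0.75 mM scaled arrays and features with every spot measured gave 1 each. At 1.5 mM values as deposited gave 6, the median of spots 2, every spot measured 2 and zeros kept 10. The trend count of 319 became 1 with scaled arrays, 160 with every spot measured, 206 with runs centred, 617 with zeros kept, 550 on a log2 dose scale, 0 with 8 arrays and 0 without the no-nickel Alexa 647 array. It ran from 0 to 512 over the fits that left out an orientation or an RNA. The any-nickel count of 267 became 1 with values as deposited, 452 with scaled arrays, 145 with every spot measured, 595 with zeros kept and 15 with 8 arrays, and ran from 28 to 1065 over the fits that left something out. Directions reversed for psmA in the trend without the no-nickel RNA (0.00489, against -0.318 without the 1.5 mM RNA), and under any nickel without Alexa 647 for bat (-0.00833, against 0.331 without Alexa 532), glyA (0.0408, against -0.385) and cheY (0.0299). Without the no-nickel Alexa 647 array they reversed again for bat (-0.0134), glyA (0.115) and cheY (0.0146), and in the trend for glyA (0.0461), a fit in which dye bias no longer cancels. The orientation is shared between doses, and differences between dye partners correlated at 0.0553 to 0.562 between RNAs; the block on orientation is the fit of 8 arrays (0 and 15). The dye-swap correlation at 0.5 mM moved to 0.716 with runs centred. Of the 21 named trend calls the rank of dose and robust eBayes kept 21, runs centred 10, the fit without the 1.5 mM RNA 6, that without the 0.75 mM RNA 5, scaled arrays 0 and the fit of the nickel RNAs alone 0. With every spot measured, 14 of the 21 could be fitted and 4 were still called. Arrays were then centred on the median of 1241 features. Of the 160 trend calls 63 were among the 319, and 79.4% were upward. The slope was 0.197 for mch, -0.131 for gdhB, -0.119 for dpsA, -0.099 for thiD and -0.0888 for psmA, each higher than in the main fit. The falls thus depend in size on the centring, as do the any-nickel differences (0.254 for mch, -0.177 for psmA). The genes truA, hutI, nadA and htr18 were not among the 14, because they lacked spots on some arrays, so their means may rest on different spots per array.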

Other observations

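The comparison of all 4 RNA samples with the reference was made after the data were seen, and its genes were chosen after their values were seen. Averaged over the 4 RNA samples, named genes differed from the single reference RNA. A bias of dyes or spots shared by all 8 arrays was not told apart from such a difference. The csg gene, which encodes the cell surface glycoprotein of the S-layer, stood at 0.489 of the reference (-0.311 ± 0.0244 log10 units, SE; limma adjusted p = 6.49e-05), below the array median in 4 of 4 RNA samples and on all 8 arrays. The enolase gene eno was at 0.617 of the reference (adjusted p = 0.000186), while tpiA of triose-phosphate isomerase and the glycerol kinase gene glpK were 1.207-fold and 1.203-fold above it (adjusted p = 0.00793 and 0.0162). All 7 measured genes of the citrate cycle list were lower, among them mdh of malate dehydrogenase at 0.667 and ppsA at 0.648 (camera adjusted p = 0.00591), as were all 6 of cobalamin and heme synthesis, including cbiG at 0.637 and cbiQ at 0.648, and 8 of 11 of motility and taxis (camera adjusted p = 0.0233 for both). With an estimated correlation the adjusted p was 0.533 for each of these 3 lists. Camera compared the lists with all features, and 62 of 129 named genes were lower, against 713 of all 2368 features. The camera p may therefore in part reflect being a named gene.

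In the other direction, pyrF of pyrimidine synthesis was 1.55-fold above the reference (adjusted p = 0.000325), the proteasome-activating ATPase gene pan1 1.51-fold (adjusted p = 0.000234) and purB of purine synthesis 1.42-fold (adjusted p = 0.000996), each in 4 of 4 RNA samples. The histidine degradation genes hutU and hutI were 1.36-fold and 1.29-fold above it; of the histidine synthesis genes hisD was 1.219-fold above it (adjusted p = 0.00853) and hisI at 0.697. Of 129 named genes 19 were higher and 62 lower, and of all 2368 features 636 and 713. The direction of the ratios is not stated; with every ratio turned, 62 named genes would be higher and 19 lower. The reference RNA is the same in all 4, so these p-values leave out its own error, and changes are relative to the array median.

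Nickel arrays lay below the no-nickel array of their own orientation at every dose, in both orientations, for 32 of 129 named genes (24.8%), and above it for 9 (6.98%). The share without any change is not known, because the no-nickel Alexa 647 array stood apart from the others and such an array lies at an end more often. Among unnamed features the shares were 12.6% and 13.2%. With every ratio turned, below and above change places. The 32 include gdhB, dpsA, psmA, psmB, thiD, htr18, glnA and proS, and also genes outside the calls, among them the chaperone gene dnaJ (0.747 of the no-nickel level at 1.5 mM), the purine synthesis genes purE and purL (0.724 and 0.729) and the ferredoxin gene fer2 (0.76); psmB and fer2 were not among them after runs of spots were centred. The named genes below and above numbered 31 and 9 with values as deposited, 29 and 8 with scaled arrays, 27 and 6 with the median of spots, 18 and 9 of 86 with every spot measured, and 38 and 10 of 133 with exact zeros kept, where the unnamed shares were 17% and 15.4%. With runs of spots centred they numbered 31 and 5, and the shares of unnamed features moved to 14.4% below and 8.04% above. This count was made after the data were seen.

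Of the tests on the disagreement of the no-nickel arrays (r = -0.135), all but that of dye bias were chosen after the result was seen. A ratio left unturned on the no-nickel Alexa 647 array alone is argued against as the whole cause. With its sign turned that array correlated at no more than -0.041 with the nickel arrays of its orientation. After runs were centred, its correlations with them, unturned, were -0.053 to 0.0681, so they were weak under either sign. Position effects, followed by spot number only, are argued against as the whole cause, since the pair correlated at -0.196 after each run of spots was centred. A no-nickel RNA too close to the reference to give signal stays open. The lowest correlation of the Alexa 532 array with the nickel arrays was 0.556. This cannot decide, because a bias of spots shared by these arrays would also make them correlate. Dye bias of single features stays open, because the difference between the 2 no-nickel arrays correlated at a median of 0.163 with that of the nickel pairs. Among the nickel pairs it was 0.477 to 0.562. A poor hybridisation of the Alexa 647 array stays open and had no test of its own. After runs were centred, the 2 pairs of spots of a feature correlated at 0.47 on that array. The value was 0.67 on its Alexa 532 partner and 0.725 to 0.92 on the nickel arrays. The median SD of repeat spots was 0.109 on it, against 0.0493 to 0.0892 on the others. Per the labels both no-nickel arrays carry the same RNA, so a biological cause cannot by itself set them apart.

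The calls of the dose trend and of any nickel were weighed next, with the test of position effects chosen after the result was seen. To weigh array noise, the deviations between dye partners alone were fitted with their signs set in 8 ways. Array noise may account for the any-nickel calls, with up to 634 against 267, although the median over the 8 ways was 1.5. For the trend there were up to 858 calls against 319, with a median of 0. These trend counts cannot decide, because the mean over doses was subtracted before the signs were set. That passes part of the large no-nickel deviation to the nickel RNAs, which some signs turn into a line along the dose. Array noise stays open for the trend calls. Chance cannot be excluded for the trend: 3 of the 24 orders of the doses gave at least as many calls, with 562 as the highest of the others. Both others also put the no-nickel and 1.5 mM RNAs at opposite ends and so resemble the real order. The reversed order gives nearly the same line with its sign turned, so a share under 0.05 was hardly possible and the orders cannot decide. For any nickel 1 of 4 choices of the lone RNA gave as many, the real one, with 0 as the highest of the others, and 4 choices are too few for a share under 0.05. Position effects cannot be told apart from dose for part of the trend calls, of which 52.4% were still called after runs were centred, and a response to nickel stays among the open explanations, untested beyond these RNA samples.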
